A study of Mus musculus with 40 samples.

How the data were processed

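Gene expression was measured by RNA sequencing in 40 libraries of HSCs and MPPs from the bone marrow of C57BL/6 mice with Mx1-Cre, WT or with floxed Hira (labelled KO). All mice received 2 doses of 20 µg poly(I:C). In the first cohort 2500 cells per library were sorted 1 week after the first dose, in 4 groups of 4 libraries (16 in all). In the H2B-GFP cohort a 6-week pulse of doxycycline (2 mg/ml in water with 10 mg/ml sucrose) was followed by a chase of 17 days, and cells were sorted by GFP when 15 days had passed since poly(I:C), in 8 groups of 3 libraries (24 in all). Libraries were made from polyA RNA by SMART-Seq2 and Nextera XT. Whether they keep the strand is not stated, so genes that overlap on opposite strands, and close paralogs, are uncertain.

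The deposited tables, 1 for each of the 6 populations, hold FPKM values per gene and library, computed by the authors. The authors' processing notes name STAR, DESeq2, HOMER and the build mm10 with no role, version or setting. In each table the median ratio of every library to the genes' geometric mean was identical, so the values carry a median-of-ratios scaling done within that table. Levels were therefore not compared between tables, and the planned tests of MPPs against HSCs and of GFP-low against GFP-high cells were not run. Differences of KO effects, each taken within a table, were tested. Genes with 0 in all libraries of a table are absent from it. All 40 value columns were used and 0 belonged to no sample. The tables of the first cohort carry Ensembl gene IDs, placed here with GENCODE coordinates, and those of the H2B-GFP cohort NCBI gene IDs, placed with RefSeq coordinates, on GRCm38 (mm10).

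Since FPKM steps by a fixed amount per read, whole read numbers were recovered for 99.95% to 99.99% of the genes of a table (within 0.01 of a whole number). These gave the depth in the report. Libraries of the first cohort held 13462 to 13972 genes at 1 FPKM or more, and those of the H2B-GFP cohort 10307 to 10794. No pair of replicates was alike beyond counting noise (chi-square per gene at least 6.98). Genes of short RNAs rest on few reads at any depth, and polyA selection does not target them. Values of replication-dependent histones show only the RNA that polyA libraries catch, so their changes need not hold for all histone mRNA.

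Tests between groups used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with empirical Bayes moderation and an intensity trend, 2-sided, within each table. The edgeR fit of counts, planned before the data were examined, was not used because the tables hold no counts. Limma replaced it, and the checks meant for counts (another normalization and another count model) were not run. Genes needed 1 FPKM or more in at least 4 libraries of the first cohort or 3 of the H2B-GFP cohort. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Adjusted p values in the report are limma's. Hira and the list levels were also compared by exact permutation of the labels, whose smallest possible p is 0.0286 for 4 against 4 and 0.1 for 3 against 3. Intervals are 95% intervals from limma.

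Before the data were examined, 29 gene lists were fixed from general knowledge. They cover the HIRA complex and H3.3, replication-dependent histones, interferon-stimulated genes, MHC class I and class II presentation, HSC-enriched genes, MPP and lymphoid priming, and the granulocyte-monocyte, erythroid and megakaryocyte lineages. Others cover mast cells with basophils and eosinophils, mature neutrophils, macrophages, B cells, T and NK cells, stroma with endothelium, DNA replication and S phase, mitosis, CDK inhibitors and quiescence, and p53 targets. The rest cover immediate-early and stress genes, inflammatory signalling, apoptosis, glycolysis, oxidative phosphorylation, ribosomal proteins, ribosome biogenesis with Myc targets, mitochondrially encoded genes and sex-linked genes. Lists with at least 5 tested members were tested with camera (limma) at the preset correlation between genes of 0.01, adjusted over 151 tests of the 6 comparisons, and again with the correlation estimated from the libraries. With so few libraries the estimate is unstable, and the preset value takes genes of a list as nearly independent. Both adjusted p values are printed. At the preset value other splits of the same libraries called a median of 8.5 to 11 lists per comparison, so a pass there is weak evidence by itself. List tests on differences of KO effects (78 tests) were added after the data were seen. List medians are of log2 differences, and list levels are means of log2(FPKM + 1) per library.

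Genes to be named followed a rule fixed beforehand. It takes up to 8 rises and 8 falls past the test with no overlap of the groups and a mean log2(FPKM + 1) of 3 or more. At any level it also takes up to 2 members of a list past the test, and 2 examples for each list that passed. Where under 10 genes passed, it takes every gene past the test and the 5 smallest p values per direction. Predicted genes with Gm or Rik names were not named by the rule. The level was written for logCPM and moved to log2(FPKM + 1) when the unit was seen. Oas3, Tspan8, Asf1b in HSCs, Klf1 and Elane in GFP-high HSCs, S100a8, Rn45s, Gstm2 in GFP-low MPPs, the chromosome 5 genes and the genes named from the mean of the GFP populations fall outside it and were chosen after their values were seen. A few genes that the rule or a later choice took up are not reported here, and the test for single libraries far from their group leaves them out. They stay in the fits, the lists and the counts of genes past the test.

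Data simulated from the spread of each table tested the procedure, with 100 genes changed by a log2 of 1 and 100 by 2. At a log2 change of 1, it recovered 92% in HSCs, 81% in MPPs, 83% and 64% in GFP-high and GFP-low HSCs and 78% and 76% in GFP-high and GFP-low MPPs, and at a log2 change of 2 at least 97%. For the differences of KO effects it recovered 68% (HSCs against MPPs), 55% (GFP-low against GFP-high HSCs) and 63% (the same in MPPs) at a log2 change of 1 and at least 94% at 2. It made 4 to 15 false calls per comparison, and 0 with no gene changed. Genes of few reads may be recovered less often.

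Settings chosen beforehand for comparison were a block by replicate number, no filter, a joint fit over tables of a cohort, each library left out in turn, an estimated correlation for the lists, and an adjusted p under 0.1 for the genes shared by HSCs and MPPs. Replicate numbers pair the GFP-low with the GFP-high libraries of a cell type and genotype, since all 12 correlations of their deviations from the group means lay at 0.13 to 0.36. Over all pairs of the 4 GFP populations they lay at -0.036 to 0.543, in 34 of 36 above every pair of unlike numbers. Added after the unit or the data were seen were a pseudocount of 0.1, libraries rescaled to one total, library quality weights, limma-voom on recovered reads and the mean of the GFP populations. Figures used Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.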

Results

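RNA from blood stem cells (HSCs) and multipotent progenitors (MPPs) of mouse bone marrow was measured in 40 libraries, which fall into 12 groups. HIRA is a chaperone that places the histone variant H3.3 on chromatin outside DNA replication, and the mice labelled KO carried a floxed Hira gene that Mx1-Cre deletes after poly(I:C), a double-stranded RNA that also induces interferon. In the first cohort, HSCs and MPPs were sorted 1 week after the first dose, with 4 WT and 4 KO libraries per cell type. In the second cohort, a pulse of H2B-GFP marked chromatin and was then diluted by division, so that GFP-high cells had divided little and GFP-low cells more. Each of its 4 populations had 3 WT and 3 KO libraries, taken 15 days after the last dose. The recovered depth was 19.93 to 27.18 M (1e6) reads per HSC library and 16.54 to 30.1 M per MPP library. It was 6.46 to 7.99 M in GFP-high HSCs, 6.34 to 9.29 M in GFP-low HSCs, 6.74 to 9.57 M in GFP-high MPPs and 5.82 to 8.95 M in GFP-low MPPs. The comparisons ask what the loss of HIRA does to gene expression in HSCs and MPPs, and whether it differs with division history.

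Hira itself, on chromosome 16 from 18877037 to 18970309 in mm10, did not differ between the labels in any of the 6 comparisons. In HSCs it stood at 1.25 ± 0.362 FPKM in WT and 1.11 ± 0.275 in the libraries labelled KO (SD, n = 4 each, log2 difference -0.09, 95% interval -0.47 to 0.29, exact permutation p = 0.543, two-sided). In MPPs it stood at 1.35 ± 0.236 against 1.19 ± 0.286 FPKM (n = 4 each, log2 -0.11, exact permutation p = 0.457). The GFP populations gave log2 differences of -0.23 in GFP-high HSCs, -0.07 in GFP-low HSCs, 0.13 in GFP-high MPPs and -0.19 in GFP-low MPPs, with 3 libraries a side, where an exact permutation p cannot go below 0.1. Between 41 and 315 reads stood behind each value. A value per gene covers all exons, so it does not show whether the floxed part is missing, and the labels remain unchecked by Hira. The groups are therefore called labelled KO.

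**Figure D1:**
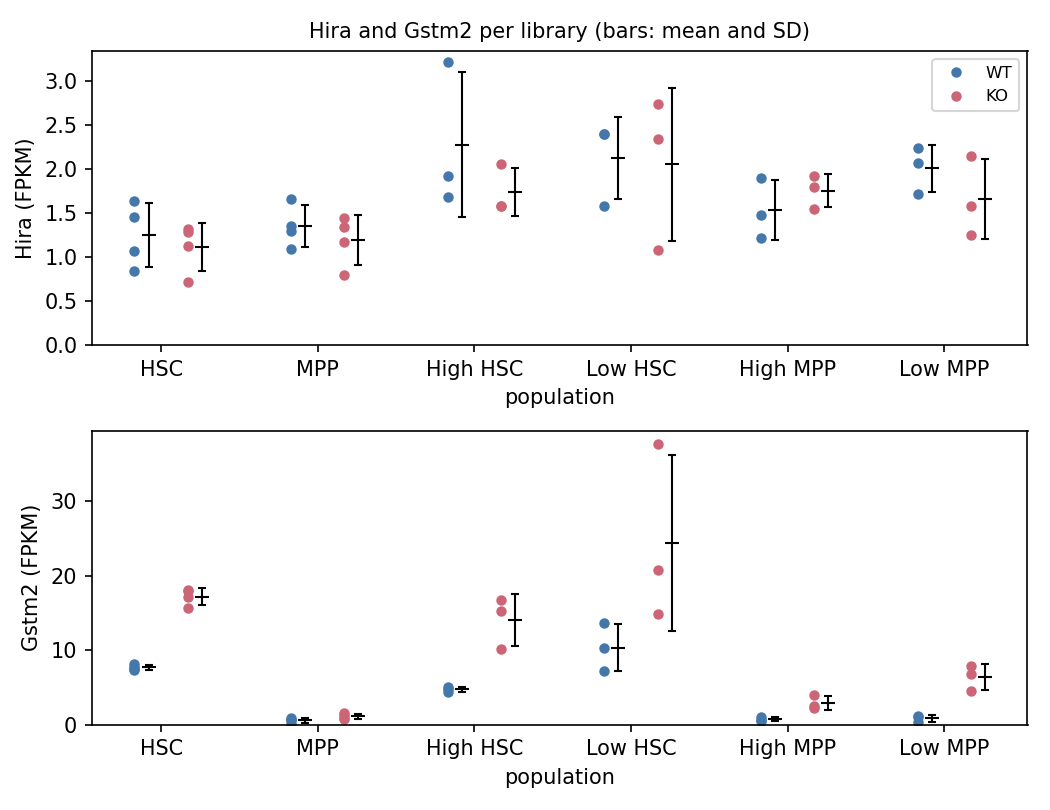
Hira (top) and Gstm2 (bottom) in FPKM per library in the 6 populations, WT in blue and labelled KO in red, with black bars for mean and SD. Hira overlaps between the labels everywhere, while Gstm2 in HSCs lies at or above 15.6 FPKM in labelled KO and at or below 8.18 in WT.

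In HSCs, labelled KO cells held more Gstm2, a glutathione S-transferase, and less Tespa1, a lymphoid gene. Gstm2 (chromosome 3, 107981702 to 107986453) rose from 7.69 ± 0.35 to 17.2 ± 1.10 FPKM (SD, n = 4 each, log2 1.06, SE 0.09, limma's adjusted p = 0.00163). Tespa1, which acts in T cell receptor signalling, fell from 10.0 ± 1.28 to 2.77 ± 0.935 FPKM (log2 -1.57, adjusted p = 0.00546). Interferon-stimulated genes had a median log2 difference of -0.20 as a group, and erythroid genes one of 0.30 (adjusted p = 0.282 and adjusted p = 0.233 with an estimated correlation).

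Of 13717 genes tested in HSCs, 17 passed, 13 higher and 4 lower in labelled KO, and 1383 reached an unadjusted p under 0.05 where 686 are expected by chance. Another split of the same 8 libraries reached 1685, so that number is not particular to the labels. The rises took in Trbv13-2, a variable segment of the T cell receptor beta locus (6.59 to 23.1 FPKM, adjusted p = 0.00276), and Selm, a selenoprotein (9.58 to 18.4 FPKM, adjusted p = 0.00982). Ppbp, a chemokine of platelets, rose from 6.76 to 17.1 FPKM (adjusted p = 0.0275), Ces2g, a carboxylesterase, from 11.1 to 25.2 (adjusted p = 0.0284), and Btg2, which restrains proliferation, from 6.78 to 14.1 (adjusted p = 0.039). Cd24a, a surface glycoprotein, rose from 104 to 165 FPKM (log2 0.66, adjusted p = 0.039), and Tspo2, an erythroid gene, from 1.21 to 5.46 (adjusted p = 0.0473). In 6.2% of the tested genes the groups did not overlap, against 2.86% by chance. The count of 17 was 8 without WT replicate 1, 11 without WT replicate 2, 10 without WT replicate 4, 9 without labelled KO replicate 2 and 11 without labelled KO replicate 3.

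The interferon-stimulated genes, the genes that cells switch on after type I interferon, fell in HSCs as a list, with 39 of 44 tested members at a negative log2 difference (adjusted p = 9.82e-08, and adjusted p = 0.282 with an estimated correlation). No member passed over all genes and 1 fell when adjusted over the list alone. Ifi35 stood at 14.9 against 19.5 FPKM (adjusted p = 0.141) and Irf9, a subunit of the factor that carries the interferon signal, at 9.29 against 12.4 (adjusted p = 0.257). The list's mean level per library was 2.81 ± 0.053 in labelled KO and 3.01 ± 0.105 in WT on the log2 scale (SD, n = 4 each, exact permutation p = 0.0286), with no overlap. Adjusted over all list levels that p is 0.332. Genes of MHC class I presentation fell too (median log2 -0.26 over 17 members, adjusted p = 1.4e-08, and adjusted p = 0.131 with an estimated correlation), with 0 members past the test over all genes and 5 lower when adjusted over the list alone. Their examples are the immunoproteasome subunits Psmb9 (37.5 against 46.1 FPKM, adjusted p = 0.236) and Psmb8 (67.1 against 84.1, adjusted p = 0.24). MHC class II presentation had a median log2 of -0.31 over 9 members (adjusted p = 0.00142, and adjusted p = 0.393 with an estimated correlation), 0 past the test over all genes and 3 lower when adjusted over the list alone. H2-DMb1, which helps load class II peptides, stood at 23.7 against 31.7 FPKM (adjusted p = 0.172).

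The erythroid list rose in HSCs (median log2 0.30 over 24 members, adjusted p = 1.64e-09, and adjusted p = 0.233 with an estimated correlation). The list's level per library gave an exact permutation p of 0.257. Tspo2 was its 1 member past the test over all genes, 9 rose when adjusted over the list alone, and Car2, carbonic anhydrase 2, stood at 592 against 399 FPKM (adjusted p = 0.0549). The megakaryocyte list rose by a median log2 of 0.08 over 24 members (adjusted p = 0.000826, and adjusted p = 0.432 with an estimated correlation), with Ppbp past the test, and 6 higher when adjusted over the list alone. Its median was 0.021 with libraries rescaled to one total. Gp9, a platelet glycoprotein, stood at 99.3 against 65.4 FPKM (adjusted p = 0.0988). The list of MPP and lymphoid priming fell (median log2 -0.29 over 12 members, adjusted p = 3.98e-05, and adjusted p = 0.284 with an estimated correlation), with Tespa1 among the members past the test and 6 lower when adjusted over the list alone. CDK inhibitors and quiescence genes rose (median log2 0.19 over 16 members, adjusted p = 0.000471, and adjusted p = 0.131 with an estimated correlation), with Btg2 past the test, and 4 higher when adjusted over the list alone. Cdkn1c, the inhibitor p57, stood at 2.88 against 1.45 FPKM (adjusted p = 0.162). Immediate-early and stress genes rose (median log2 0.21 over 20 members, adjusted p = 0.00229, and adjusted p = 0.378 with an estimated correlation), with 2 members higher when adjusted over the list alone. Fos stood at 18.6 against 9.08 FPKM (adjusted p = 0.0573) and Zfp36, which destabilises mRNA, at 10.8 against 6.84 (adjusted p = 0.13). Macrophage genes, markers of another cell type, rose by a median log2 of 0.54 over 8 members (adjusted p = 3.44e-05, and adjusted p = 0.131 with an estimated correlation), with 4 higher when adjusted over the list alone. The complement gene C1qb stood at 11 against 5.95 FPKM (adjusted p = 0.13).

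DNA replication genes fell in HSCs (median log2 -0.15 over 42 members, adjusted p = 8.28e-06, and adjusted p = 0.484 with an estimated correlation), while mitosis genes rose (0.12 over 46 members, adjusted p = 8.62e-05, and adjusted p = 0.432 with an estimated correlation). Mcm7, a subunit of the replicative helicase, stood at 42.7 against 53.2 FPKM (adjusted p = 0.284), and Ube2c, which drives exit from mitosis, at 53.9 against 41.3 (adjusted p = 0.13). The mitosis median was 0.057 with libraries rescaled to one total. Glycolysis genes fell by a median log2 of 0.14 (adjusted p = 0.00116, and adjusted p = 0.432 with an estimated correlation), with Pkm at 141 against 184 FPKM (adjusted p = 0.162). A further 5 lists passed with all libraries and were lost in fits without 1 library. One was replication-dependent histones (0.10, adjusted p = 0.00895, but 0.862 without labelled KO replicate 4, and lost without WT 2 or KO 3 too). Another was granulocyte-monocyte genes (0.16, adjusted p = 0.044, but 0.166 without WT replicate 1, and lost without WT 2, WT 4, KO 1, KO 2 or KO 3 too). Ribosomal proteins (0.09, adjusted p = 0.000617) were lost without WT 2 (0.451) or KO 4 (0.277). Ribosome biogenesis and Myc targets (-0.10, adjusted p = 0.00874) were lost without WT 1 (0.284) or KO 4 (0.491), and mitochondrially encoded genes (0.22, adjusted p = 0.00507) without WT 2 (0.0879), WT 4 (0.1) or KO 4 (0.201). Their adjusted p values with an estimated correlation were 0.735, 0.516, 0.735, 0.671 and 0.607 in that order. With libraries rescaled to one total the medians of the first 4 were 0.031, 0.093, 0.019 and -0.165, and that of glycolysis -0.203.

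In MPPs, the lists of mitosis and of mast cells and basophils were higher in labelled KO and that of interferon-stimulated genes was lower, all 3 at the preset correlation alone (adjusted p = 0.378, 0.393 and 0.432 with an estimated one). All 44 tested mitosis genes were higher, by a median log2 of 0.65, with 0 past the test over all genes. Cpa3, the carboxypeptidase of mast cell granules (chromosome 3, 20215620 to 20242181), rose from 5.39 ± 0.83 to 16 ± 3.04 FPKM (SD, n = 4 each, log2 1.40, SE 0.16, adjusted p = 0.0161). Asf1b, a chaperone that carries new histones H3 and H4, rose from 14.6 ± 2.95 to 29.3 ± 2.72 FPKM (log2 0.97, adjusted p = 0.0429). Kpna2, a nuclear import receptor, rose from 23.9 ± 5.59 to 51.6 ± 8.22 (log2 1.09, adjusted p = 0.0475).

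Of 13916 genes tested in MPPs, 15 passed, 4 higher and 11 lower in labelled KO, and 2305 reached an unadjusted p under 0.05 where 696 are expected by chance (2186 in another split of the libraries). The balance of directions depends on the fit, with 322 higher and 258 lower in a joint fit with HSCs, 122 and 125 with quality weights and 48 and 59 with voom. Bex4 rose from 13 to 37.2 FPKM (adjusted p = 0.0424) and Fam69b fell from 24.3 to 12.3 (log2 -0.92, adjusted p = 0.0267). A further 4 of the 11 falls lie in one stretch of chromosome 5 (see other observations). Trbd1, Trbj1-5, Mir5123 and Gm24620, short genes with at most 4 reads in their lowest library, fell too. In 9.92% of genes the groups did not overlap, against 2.86% by chance. The count of 15 was 0 without WT 2 and 194 without KO 4, the library that stood farthest from the others. It was 61 without WT 3, 3 without WT 4, 5 without KO 1 or 2, and 4 without KO 3.

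The mitosis list rose in MPPs (adjusted p = 4.86e-20, and adjusted p = 0.378 with an estimated correlation), with 0 members past the test over all genes and 30 higher when adjusted over the list alone. Ccnb1, cyclin B1, stood at 27.3 against 10.2 FPKM (log2 1.37, adjusted p = 0.0514) and Birc5, the spindle protein survivin, at 30.9 against 13.8 (log2 1.15, adjusted p = 0.0524). The list's level was 3.69 ± 0.25 in labelled KO and 3.00 ± 0.306 in WT (n = 4 each, exact permutation p = 0.0286, and 0.332 adjusted over all list levels). DNA replication genes rose by a median log2 of 0.36 (40 of 42 members positive, adjusted p = 2.09e-10, and adjusted p = 0.432 with an estimated correlation), with 6 higher when adjusted over the list alone. Their examples are Rrm2, a subunit of ribonucleotide reductase (61.9 against 31.9 FPKM, adjusted p = 0.0514), and Slbp, which binds histone mRNA (47.9 against 30.3, adjusted p = 0.0514). Replication-dependent histones rose by 0.24 (54 members, adjusted p = 0.000133, and adjusted p = 0.499 with an estimated correlation), with 0 past the test and Hist1h4c at 21.3 against 14.1 FPKM (adjusted p = 0.131). The list of the HIRA complex and H3.3, which takes in other histone chaperones, rose by 0.22 over 15 members (adjusted p = 0.00436, and adjusted p = 0.346 with an estimated correlation). Its 1 member past the test was Asf1b, and its relative Asf1a stood at 36.2 against 25.3 FPKM (adjusted p = 0.133). Oxidative phosphorylation genes rose by 0.29, positive in 72 of 74 members with 0 past the test (adjusted p = 3.44e-11, and adjusted p = 0.47 with an estimated correlation).

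Erythroid genes rose in MPPs by a median log2 of 0.98, positive in 24 of 26 members (adjusted p = 1.62e-08, and adjusted p = 0.432 with an estimated correlation), with 0 past the test over all genes and 12 higher when adjusted over the list alone. The list's level gave an exact permutation p of 0.143. Tfrc, the transferrin receptor, stood at 18 against 8.64 FPKM (adjusted p = 0.0514) and Car2 at 592 against 332 (adjusted p = 0.0748). Genes of mast cells, basophils and eosinophils rose by 1.71 (all 10 members positive, adjusted p = 7.9e-06, and adjusted p = 0.393 with an estimated correlation), with Cpa3 past the test. The basophil protease Mcpt8 stood at 19.8 against 3.12 FPKM (adjusted p = 0.0514). Interferon-stimulated genes fell by a median log2 of 0.28, negative in 42 of 46 members (adjusted p = 2.36e-07, and adjusted p = 0.432 with an estimated correlation), with 0 past the test over all genes and 2 lower when adjusted over the list alone. The list's level gave an exact permutation p of 0.0857. Ifi44 stood at 4.47 against 8.09 FPKM (adjusted p = 0.0686) and Isg15, a ubiquitin-like modifier, at 8.11 against 14.6 (adjusted p = 0.0956). MHC class I presentation fell by 0.28 over 17 members (adjusted p = 2.65e-05, and adjusted p = 0.346 with an estimated correlation), with H2-Q4 at 14.0 against 20.4 FPKM (adjusted p = 0.0759). Inflammatory signalling genes fell by 0.28 over 28 members (adjusted p = 2.65e-05, and adjusted p = 0.131 with an estimated correlation), with Il1r1, the interleukin 1 receptor, at 5.17 against 8.21 FPKM (adjusted p = 0.103).

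A further 4 MPP lists passed and were lost in fits without 1 library. HSC-enriched genes (median log2 -0.14 over 38 members, adjusted p = 0.0256, and adjusted p = 0.432 with an estimated correlation) were lost without WT 2 (0.113) or KO 2 (0.0566). Their example Ly6a, the stem cell antigen Sca-1, stood at 105 against 160 FPKM (adjusted p = 0.0768). B cell genes (-1.02 over 6 members, adjusted p = 0.0243, and adjusted p = 0.346 with an estimated correlation) were lost without WT 2 (-0.47, adjusted p = 0.0946). Vpreb1, part of the pre-B cell receptor, stood at 1.44 against 3.65 FPKM (adjusted p = 0.0866). MHC class II presentation (-0.24, adjusted p = 0.039, and adjusted p = 0.516 with an estimated correlation) was lost without WT 2 (0.101), WT 3 (0.0933), KO 2 (0.0508) or KO 3 (0.201). Mitochondrially encoded genes (0.18, adjusted p = 0.0393, and adjusted p = 0.687 with an estimated correlation) were lost without WT 4 (0.639), KO 2 (0.0517) or KO 3 (0.203). After rescaling to one total the HSC-enriched median was -0.221 and the mitochondrial one 0.107.

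The KO effects in HSCs and MPPs were then set against each other, to ask whether the cell types respond alike. The effect on the mitosis and DNA replication lists was lower in HSCs than in MPPs, with a median log2 difference of -0.55 (adjusted p = 3.58e-18, and adjusted p = 0.318 with an estimated correlation) and -0.54 (adjusted p = 1.02e-21, and adjusted p = 0.23 with an estimated correlation). Of 14923 genes tested, 5 passed, 4 higher and 1 lower. Tmem158 fell in MPPs from 5.84 to 1.54 FPKM (adjusted p = 0.0111) and stood at 3.00 and 2.67 in HSCs, a difference of effects of 1.31 (SE 0.21, adjusted p = 0.0341), and Mir3060, a short RNA gene, gave -1.42 (adjusted p = 0.016). The other 3 are the chromosome 5 genes 1700003C15Rik, Gm43643 and RP23-92D22.3, which held 0, 0 and 0.605 FPKM in WT HSCs. They had no room to fall there, so for them the difference does not show another response in HSCs. Asf1b stood at 40.8 FPKM in both HSC groups, a difference of effects of -0.97 (adjusted p = 0.087). Among the 26 lists, 12 passed in all and 0 of them with an estimated correlation, where the smallest adjusted p = 0.23. In every fit without 1 library 4 of the 12 held: DNA replication, mitosis, oxidative phosphorylation (-0.24, adjusted p = 6.86e-10, and -0.358 without labelled KO MPP replicate 4) and immediate-early genes (0.23, adjusted p = 0.000595). The other 8 were each lost without at least 1 library. Among those lower in HSCs, the erythroid difference (-0.38) came to 0.02 without WT MPP replicate 1 (adjusted p = 0.745), and that of mast cell genes (-0.54) to 0.044 without labelled KO MPP replicate 2 (adjusted p = 0.148). Without labelled KO HSC replicate 4, ribosome biogenesis and Myc targets (-0.16) came to -0.068 (adjusted p = 0.273) and HIRA complex genes (-0.15) to -0.061 (adjusted p = 0.118). Of those higher in HSCs, inflammatory genes (0.16) came to 0.099 without WT HSC replicate 1 (adjusted p = 0.0954) and megakaryocyte genes (0.11) to 0.033 without WT MPP replicate 2 (adjusted p = 0.213). HSC-enriched (0.18) and B cell genes (0.69) were lost without WT MPP replicate 2 as well (adjusted p = 0.0522 and 0.0594), and reached 0.112 without WT HSC replicate 1 and 0.405 without labelled KO MPP replicate 4. The 5 gene calls became 0 without WT HSC replicate 2, labelled KO HSC replicate 4 or WT MPP replicate 2, and 20 without WT MPP replicate 3. No gene was called in both cell types in the same direction at an adjusted p under 0.05, against 0.0033 higher and 0.0012 lower by chance among 13166 genes tested in both. At an adjusted p under 0.1 the same count was 8, with 5 higher and 3 lower, against 0.245 and 0.0936 by chance.

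**Figure D2:**
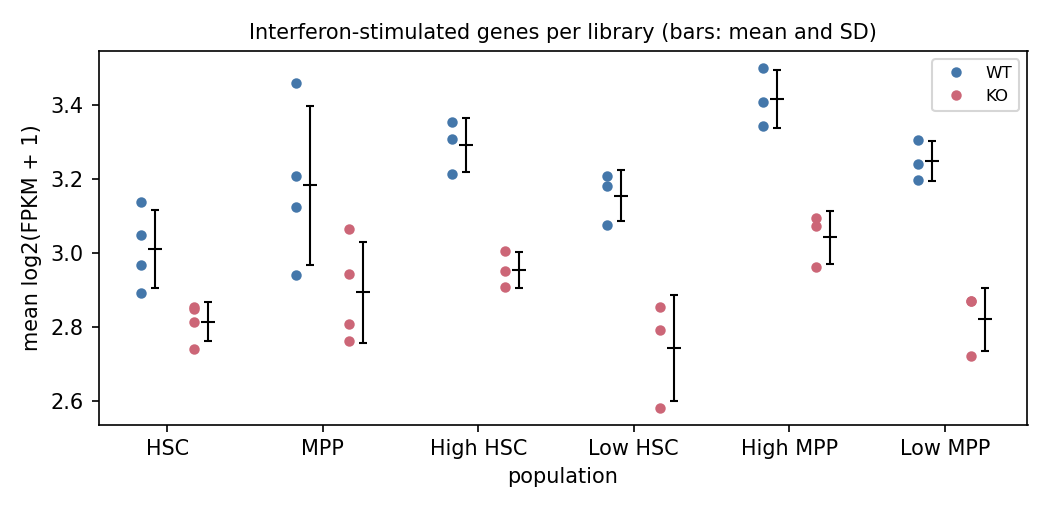
Mean log2(FPKM + 1) of the interferon-stimulated genes per library in the 6 populations, WT in blue and labelled KO in red, with black bars for mean and SD. Labelled KO libraries lie below every WT library in 5 of the 6 populations, while in MPPs the highest labelled KO library (3.06) passes the lowest WT library (2.94).

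In GFP-high HSCs, the cells that had divided least, the lists of DNA replication, mitosis and histones were lower in labelled KO at the preset correlation alone (adjusted p = 0.393, 0.432 and 0.186 with an estimated one), with 0 members past the test over all genes. All 42 tested DNA replication genes were lower, with a median log2 difference of -0.33, and so were all 46 mitosis genes, with -0.35. Prtn3, a protease of neutrophil granules (chromosome 10, 79879667 to 79883174), rose from 174 ± 9.88 to 294 ± 12.8 FPKM (SD, n = 3 each, log2 0.76, SE 0.09, adjusted p = 0.0383). The granulocyte-monocyte list to which it belongs did not move with it (median -0.12, 11 of 27 members positive, adjusted p = 0.54), and the neighbouring Elane, another protease of these granules, stood lower, at 59.0 against 158 FPKM (log2 -1.53, adjusted p = 0.225). Ptgds, which makes prostaglandin D, rose from 1.58 ± 0.236 to 4.93 ± 0.257 (log2 1.21, adjusted p = 0.0383). The third call among 10850 genes was the short Mir6999, listed at 0 in all WT libraries and 1.57 FPKM in labelled KO. Gstm2 stood at 14.0 against 4.71 FPKM (log2 1.37, adjusted p = 0.0528), and lower values that did not pass included H4c4, an H4 histone (12.9 against 23.5, adjusted p = 0.122), and Nenf (33.8 against 53.2, adjusted p = 0.107). An unadjusted p under 0.05 was reached by 1124 genes where 542 are expected (713 in another split), and 16.07% did not overlap against 10% by chance. The count of 3 fell to 0 without any 1 of the 3 WT libraries or labelled KO replicates 2 or 3.

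The DNA replication list fell in GFP-high HSCs (adjusted p = 1.24e-16, and adjusted p = 0.393 with an estimated correlation), with 0 members past the test over all genes and 10 lower when adjusted over the list alone. Dscc1 stood at 1.70 against 3.25 FPKM (adjusted p = 0.2). The mitosis list fell (adjusted p = 4.15e-14, and adjusted p = 0.432 with an estimated correlation), with 2 lower when adjusted over the list alone and Top2a, topoisomerase II, at 6.11 against 10.8 FPKM (adjusted p = 0.2). Replication-dependent histones fell by 0.52 (36 members, adjusted p = 1.69e-09, and adjusted p = 0.186 with an estimated correlation), with 0 past the test, 13 lower and 2 higher when adjusted over the list alone. Interferon-stimulated genes fell by 0.30, negative in 43 of 46 members (adjusted p = 4.38e-14, and adjusted p = 0.131 with an estimated correlation), with 1 lower when adjusted over the list alone. Ifi44 stood at 5.33 against 9.55 FPKM (adjusted p = 0.184). MHC class I presentation fell by 0.18 over 16 members (adjusted p = 0.000118, and adjusted p = 0.432 with an estimated correlation). HSC-enriched genes rose by 0.11 over 44 members (adjusted p = 0.00115, and adjusted p = 0.432 with an estimated correlation), with 4 higher when adjusted over the list alone. Kit, the stem cell factor receptor, stood at 154 against 111 FPKM (adjusted p = 0.2) and the adhesion protein Esam at 74.7 against 51.5 (adjusted p = 0.2). Immediate-early and stress genes rose by 0.33 over 20 members (adjusted p = 0.000492, and adjusted p = 0.432 with an estimated correlation), with Ier3 at 51.8 against 31.8 FPKM (adjusted p = 0.195). The medians of MHC class I and HSC-enriched genes were -0.105 and 0.183 with libraries rescaled to one total.

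A further 6 lists passed in GFP-high HSCs and were lost in fits without 1 library. Erythroid genes (median log2 -0.30 over 24 members, adjusted p = 0.0394, and adjusted p = 0.66 with an estimated correlation) went the other way than in the other 5 comparisons. They were lost without WT 1 (-0.07, adjusted p = 0.796), KO 2 (0.226) or KO 3 (0.301), and Car1, carbonic anhydrase 1, stood at 48.6 against 121 FPKM (adjusted p = 0.293). MHC class II presentation (-0.26, adjusted p = 0.00621) was lost without KO 3 (0.196), and Cd74, the class II invariant chain, stood at 43.3 against 95.3 FPKM (adjusted p = 0.37). Ribosomal proteins (-0.07, adjusted p = 0.00017) were lost without KO 3 (0.196) and oxidative phosphorylation (-0.07, adjusted p = 0.000492) without WT 1 (0.0743) or KO 2 (0.143). With libraries rescaled to one total both medians turned to 0.01, and the ribosomal protein call was lost (adjusted p = 0.0536). The p53 targets (0.13, adjusted p = 0.0383) were lost without WT 1, WT 3, KO 1 or KO 2 (highest 0.133) and glycolysis (0.10, adjusted p = 0.044) without WT 2, WT 3, KO 1 or KO 3 (highest 0.193). The same rescaling lost the p53 call (adjusted p = 0.0719) and gave a glycolysis median of 0.177. Their adjusted p values with an estimated correlation were 0.516, 0.66, 0.66, 0.393 and 0.432 from MHC class II on.

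In GFP-low HSCs, which had divided more, the erythroid list was higher in all 24 tested members, by a median log2 of 0.78, and interferon-stimulated genes had a median of -0.35 (adjusted p = 0.393 and adjusted p = 0.251 with an estimated correlation). Among single genes, Rhag, a membrane protein of red cells, stood at 15.1 ± 4.51 against 3.12 ± 0.797 FPKM (SD, n = 3 each, log2 1.94, SE 0.24, adjusted p = 0.0858). Klf1, the master regulator of erythroid genes, stood at 29.6 ± 15.1 against 9.20 ± 2.05 (log2 1.48, adjusted p = 0.245). Dok2, an adaptor of kinase signalling, stood at 61.9 against 28.0 FPKM (adjusted p = 0.0858), Gadd45g, a stress gene, at 20.7 against 6.01 (adjusted p = 0.0858) and Cd24a at 217 against 117 (log2 0.88, adjusted p = 0.0858). With limma 0 of 10705 genes passed, 917 reached an unadjusted p under 0.05 where 535 are expected (909 in another split), and voom on recovered reads also gave 0. A joint fit of the 4 GFP populations gave 54 (34 higher and 20 lower) and quality weights gave 3. The groups did not overlap in 14.09% of genes, against 10% by chance, and the count of 0 was 9 without labelled KO replicate 1.

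The erythroid list rose in GFP-low HSCs (adjusted p = 1.43e-13, and adjusted p = 0.393 with an estimated correlation), with 14 members higher when adjusted over the list alone. The beta globin gene Hbb-bt stood at 371 against 74.5 FPKM (adjusted p = 0.239), with labelled KO replicate 3 highest at 657 FPKM. Interferon-stimulated genes fell (41 of 45 members negative, adjusted p = 4.04e-13, and adjusted p = 0.251 with an estimated correlation), with 0 past the test over all genes and 11 lower when adjusted over the list alone. Rtp4 stood at 9.82 against 20.5 FPKM (adjusted p = 0.216). Replication-dependent histones fell by 0.36 over 40 members (adjusted p = 7.18e-05, and adjusted p = 0.432 with an estimated correlation), with 8 lower when adjusted over the list alone. H2ac8 stood at 10.3 against 25.2 FPKM and H4c3 at 0.845 against 3.17 (adjusted p = 0.168 each). These 3 list calls held in every fit without 1 library, and the other 10 did not.

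Labelled KO replicate 3 of the GFP-low HSCs held 13430 FPKM of the neutrophil gene S100a8, while the other 5 libraries held 1108 to 2234. The mature neutrophil list rose by 1.05 (all 15 members positive, adjusted p = 3.08e-05, and adjusted p = 0.536 with an estimated correlation), but its median was -0.09 without that library (adjusted p = 0.938). Without it, the calls of granulocyte-monocyte genes (0.50, adjusted p = 3.38e-06, then 0.374), MHC class I presentation (-0.22, adjusted p = 0.000128, then 0.13) and MHC class II presentation (-0.30, adjusted p = 0.00874, then 0.407) were lost. Tap1, the peptide transporter, stood at 29.4 against 40.6 FPKM (adjusted p = 0.54). Without labelled KO replicate 1 the calls of DNA replication (-0.23, adjusted p = 2.65e-05, then 0.0578), mitosis (-0.16, adjusted p = 0.00318, then 0.873), CDK inhibitors and quiescence (0.18, adjusted p = 0.00826, then 0.0762) and megakaryocyte genes (0.10, adjusted p = 0.0284, then 0.34) were lost. Btg2 stood at 8.90 against 2.72 FPKM (adjusted p = 0.245) and the platelet integrin Itga2b at 53 against 23.7 (adjusted p = 0.168). Immediate-early and stress genes (0.24, adjusted p = 0.00427) were lost without WT 1 (0.0731) or KO 3 (0.078), and oxidative phosphorylation (0.08, adjusted p = 0.0105) without WT 3 (0.857), KO 2 (0.0536) or KO 3 (0.695), and its median was 0.037 with libraries rescaled to one total. MHC class II was lost without WT 1 too (0.056), megakaryocyte genes without WT 2 (0.0541) and mitosis without WT 2 (0.0941) or KO 2 (0.0788). With an estimated correlation the adjusted p of these 9 lists after the neutrophil list was 0.516, 0.516, 0.53, 0.509, 0.723, 0.385, 0.378, 0.432 and 0.789 in the order named.

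In GFP-high MPPs, the lists of histones and of interferon-stimulated genes were lower in labelled KO at the preset correlation alone (adjusted p = 0.123 and 0.131 with an estimated one). Replication-dependent histones, whose mRNAs are made as DNA replicates, had a median log2 difference of -0.62, negative in 30 of 34 members, and interferon-stimulated genes one of -0.36, negative in 44 of 46. The libraries were made from polyA RNA, so the histone values show only RNA caught that way. H2ac8 stood at 7.15 ± 0.66 against 21.1 ± 5.59 FPKM (SD, n = 3 each, log2 -1.41, SE 0.19, adjusted p = 0.128) and the linker histone H1f4 at 2.12 ± 0.508 against 6.00 ± 0.52 (log2 -1.18, adjusted p = 0.128). Mapk13, a p38 kinase, stood at 4.51 against 1.66 FPKM (adjusted p = 0.128), Dok2 at 60.7 against 29.5 (adjusted p = 0.128) and the keratin Krt80 at 4.23 against 1.03 (adjusted p = 0.234). With limma 0 of 10789 genes passed, 765 reached an unadjusted p under 0.05 where 539 are expected, and voom also gave 0, while a joint fit of the 4 GFP populations gave 5. Another split of the same 6 libraries reached 935, so that number is not particular to the labels. The groups did not overlap in 13.33% of genes, against 10% by chance, and the count of 0 was 3 without labelled KO replicate 1 and 1 without labelled KO replicate 3.

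The histone list fell in GFP-high MPPs (adjusted p = 6.83e-14, and adjusted p = 0.123 with an estimated correlation), with 0 members past the test over all genes, 14 lower and 2 higher when adjusted over the list alone. Interferon-stimulated genes fell (adjusted p = 1.86e-18, and adjusted p = 0.131 with an estimated correlation), with 3 lower when adjusted over the list alone. Ifi44 stood at 4.51 against 9.51 FPKM (log2 -0.93, adjusted p = 0.128) and Phf11b at 13.4 against 20.0 (adjusted p = 0.397). MHC class I presentation fell by 0.30 (all 16 members negative, adjusted p = 1.15e-06, and adjusted p = 0.432 with an estimated correlation), with Tap1 at 31.3 against 44.4 FPKM (adjusted p = 0.592). DNA replication genes fell by 0.35 (38 of 42 members negative, adjusted p = 9.12e-13, and adjusted p = 0.432 with an estimated correlation), with Gins2 at 4.44 against 6.82 FPKM (adjusted p = 0.492). Ribosomal proteins fell by 0.22 (72 of 77 members negative, adjusted p = 7.32e-14, and adjusted p = 0.509 with an estimated correlation). The ribosomal protein median was -0.117, and that of MHC class I -0.201, with libraries rescaled to one total. Genes of mast cells, basophils and eosinophils rose by 0.87 over 8 members (adjusted p = 0.000617, and adjusted p = 0.432 with an estimated correlation), with 2 higher when adjusted over the list alone. Cpa3 stood at 4.54 against 1.66 FPKM (adjusted p = 0.47) and Mcpt8 at 2.06 against 0.344 (adjusted p = 0.381).

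Labelled KO replicate 3 of the GFP-high MPPs held 11260 FPKM of S100a8, while the other 5 libraries held 1685 to 3102. The mature neutrophil list rose by 1.06 (all 14 members positive, adjusted p = 3.6e-09, and adjusted p = 0.432 with an estimated correlation) and by 0.33 without that library (adjusted p = 0.000173). Granulocyte-monocyte genes rose by 0.64 over 27 members (adjusted p = 1.93e-08, and adjusted p = 0.393 with an estimated correlation) and by 0.25 without it, with Prtn3 at 297 against 190 FPKM (adjusted p = 0.381). The erythroid call (0.18 over 24 members, adjusted p = 0.0308, and adjusted p = 0.724 with an estimated correlation) turned to -0.25 without it (adjusted p = 0.058) and was lost without WT 2 (adjusted p = 0.705). The MHC class II call (-0.21, adjusted p = 0.00133, and adjusted p = 0.461 with an estimated correlation) was lost without it (adjusted p = 0.241). Calls lost without other libraries too were mitosis (-0.22, adjusted p = 6.04e-05, then 0.287 without KO 1), megakaryocyte (0.13, adjusted p = 0.00436, then 0.0859 without KO 2) and immediate-early and stress genes (0.21, adjusted p = 0.00102, then 0.0707 without WT 1 and 0.0516 without KO 2). Macrophage genes (0.28, adjusted p = 0.017) were lost without WT 1 (0.146), KO 2 (0.126) or KO 3 (0.106), and genes of stroma and endothelium (0.30, adjusted p = 0.044) without WT 1 (0.161), WT 2 (0.291), KO 1 (0.136) or KO 2 (0.126). With an estimated correlation the adjusted p of these 5 lists was 0.64, 0.284, 0.432, 0.497 and 0.432 in the order named. With libraries rescaled to one total the medians of MHC class II, mitosis and megakaryocyte genes were -0.11, -0.134 and 0.224. The calls of erythroid (adjusted p = 0.165), macrophage (adjusted p = 0.0783) and stroma genes (adjusted p = 0.103) were lost with it.

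In GFP-low MPPs, the erythroid list was higher in labelled KO at the preset correlation alone (adjusted p = 0.274 with an estimated one), with 4 of 24 members past the test over all genes. Epor, the erythropoietin receptor (chromosome 9, 21958897 to 21963576), rose from 7.43 ± 0.858 to 20.1 ± 2.66 FPKM (SD, n = 3 each, log2 1.32, SE 0.14, adjusted p = 0.0228). Gata1, the transcription factor of red cell and platelet precursors, rose from 7.22 ± 1.73 to 24.6 ± 7.44 (log2 1.62, adjusted p = 0.035). The water channel Aqp1 rose from 27.1 to 75.6 FPKM (log2 1.46, adjusted p = 0.035) and Rhag from 5.42 to 25.3 (log2 2.00, adjusted p = 0.035). Parp9 and Gbp2, both induced by interferon, fell from 9.12 to 4.67 (log2 -0.84, adjusted p = 0.0421) and from 23.4 to 12.3 FPKM (log2 -0.88, adjusted p = 0.0468). None of the genes of this comparison passed in the fits without WT 3, KO 2 (the male) or KO 3.

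Of 10621 genes tested in GFP-low MPPs, 34 passed, 24 higher and 10 lower, and 1304 reached an unadjusted p under 0.05 where 531 are expected (729 in another split). Further rises were Spp1, the matrix protein osteopontin (4.59 to 16.1 FPKM, adjusted p = 0.0238), Gstm5 (31.8 to 68.5, adjusted p = 0.0238) and its relative Gstm2 (0.824 to 6.36, log2 2.01). The protease genes Prss50 (4.30 to 18.1 FPKM) and Ctse (31.7 to 74.2) and the immediate-early Nr4a1 (0.887 to 3.67) also rose. Further falls were Ctsw, a protease of cytotoxic lymphocytes (16.7 to 4.85 FPKM, log2 -1.62, adjusted p = 0.0238), F2r, the thrombin receptor (13.5 to 5.88, adjusted p = 0.0421), the desaturase Scd2 (26.7 to 16, adjusted p = 0.0421) and H4c4 (22.9 to 12.1, adjusted p = 0.035). The groups did not overlap in 19.06% of genes, against 10% by chance. The count of 34 was 0 without WT 3, KO 2 or KO 3, 2 without WT 2 and 13 without WT 1. Mir103-2, Mir6955, Mir7001, Mir421 and Mir1962, short genes with at most 1 read in their lowest library, passed too.

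The erythroid list rose in GFP-low MPPs by a median log2 of 0.82 (21 of 24 members positive, adjusted p = 1.35e-14, and adjusted p = 0.274 with an estimated correlation), with 4 members past the test over all genes, Epor and Aqp1 among them, and 17 higher when adjusted over the list alone. Interferon-stimulated genes fell by 0.36 (44 of 46 negative, adjusted p = 3.74e-15, and adjusted p = 0.131 with an estimated correlation), with 3 past the test over all genes and 16 lower when adjusted over the list alone. The 3 were Parp9, Gbp2 and Oas3, a sensor of double-stranded RNA (log2 -0.78), and Oas3 is named as the third, after its value was seen. MHC class I presentation fell by 0.38 (all 16 members negative, adjusted p = 2.73e-08, and adjusted p = 0.393 with an estimated correlation), with 5 lower when adjusted over the list alone. Tapbp, which loads class I peptides, stood at 55.3 against 79.7 FPKM (adjusted p = 0.148). Replication-dependent histones fell by 0.55 over 40 members (adjusted p = 6.75e-05, and adjusted p = 0.432 with an estimated correlation), with H4c4 past the test and 6 lower when adjusted over the list alone. Inflammatory signalling genes fell by 0.26 over 30 members (adjusted p = 0.000492, and adjusted p = 0.432 with an estimated correlation), with Il18 at 17.6 against 35.8 FPKM (adjusted p = 0.226). The call of DNA replication (-0.17, adjusted p = 0.00186) was lost without KO 2 (0.321) and that of MHC class II presentation (-0.46, adjusted p = 0.00888) without KO 2 (0.0847) or KO 3 (0.237). The calls of oxidative phosphorylation (0.14, adjusted p = 2.15e-05) without KO 3 (0.12), ribosome biogenesis and Myc targets (0.14, adjusted p = 0.00162) without WT 2 (0.244) or KO 3 (0.283) and ribosomal proteins (-0.05, adjusted p = 0.0243) without WT 1 (0.169), KO 2 (0.613) or KO 3 (0.0551) were lost as well. The ribosomal protein median turned to 0.01 with libraries rescaled to one total (adjusted p = 0.165). With an estimated correlation the adjusted p of these 5 lists was 0.64, 0.573, 0.66, 0.66 and 0.86 in the order named.

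**Figure D3:**
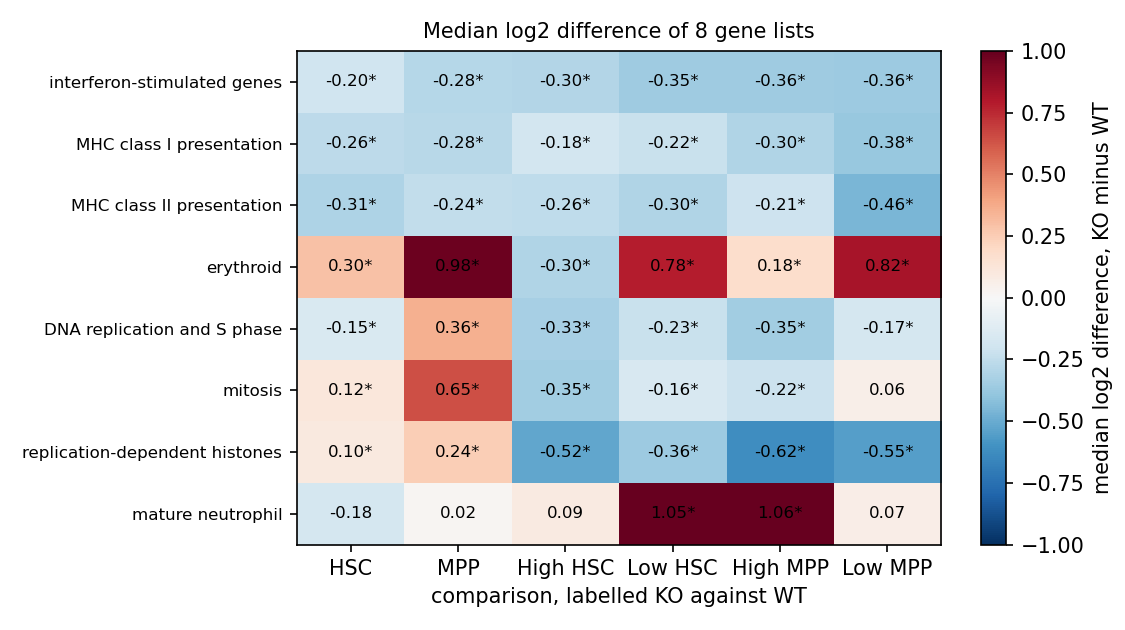
Median log2 difference, labelled KO minus WT, of 8 gene lists (down) in the 6 comparisons (across), where an asterisk marks an adjusted p under 0.05 with the preset correlation. Interferon-stimulated genes are negative in all 6 columns (-0.20 to -0.36), and with an estimated correlation 0 of the list calls passed.

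The KO effects in GFP-low and GFP-high cells were set against each other to ask whether division history changes the response. In HSCs the effect on erythroid genes was higher in GFP-low than in GFP-high cells by a median log2 of 1.25 (adjusted p = 5.28e-17, and adjusted p = 0.23 with an estimated correlation). It held in all 12 fits without 1 library, at 0.891 to 1.475. The part from GFP-high cells, where the list stood at -0.30 (adjusted p = 0.0394, and adjusted p = 0.66 with an estimated correlation), rested on WT replicate 1, without which it was -0.075 (adjusted p = 0.796). In GFP-low HSCs the 2 globin genes stood 1.35 above the other members. Klf1 had effects of 1.48 and -0.41 (-0.105 without WT replicate 1 of the GFP-high HSCs), a difference with an adjusted p = 0.999. With limma 0 of 11284 genes passed for this difference and 394 reached an unadjusted p under 0.05 where 564 are expected. In MPPs the erythroid effect was also higher in GFP-low cells, by 0.62 (adjusted p = 2.66e-05, and adjusted p = 0.658 with an estimated correlation). That difference ranged from 0.309 without labelled KO replicate 2 of the GFP-high MPPs to 1.095 without replicate 3, and the effect in GFP-high MPPs itself (0.18) turned to -0.25 without that replicate 3. Of 11237 genes tested, 1 passed, the short Mir7001 (2.44, adjusted p = 0.00123, but 0.0516 with a block by replicate number, which pairs these libraries), and 314 reached an unadjusted p under 0.05. Mitosis genes had the higher effect in GFP-low cells in HSCs (0.23, adjusted p = 0.00153, and adjusted p = 0.684 with an estimated correlation) and in MPPs (0.32, adjusted p = 8.22e-06, and adjusted p = 0.658 with an estimated correlation). Without labelled KO replicate 3 of the GFP-low HSCs the first came to 0.023 (adjusted p = 0.874), and 3 other libraries also took it away. The second was lost without KO 1 of the GFP-high MPPs (0.126, adjusted p = 0.0672) and stood at 0.631 without KO 3. In all, 8 lists passed in HSCs and 12 in MPPs, 3 and 5 of them in every fit without 1 library, and 0 did with an estimated correlation. The neutrophil differences (1.08 in HSCs, -0.97 in MPPs) came to -0.064 without labelled KO replicate 3 of the GFP-low HSCs (adjusted p = 0.53) and to -0.294 without that of the GFP-high MPPs (adjusted p = 0.285). Granulocyte-monocyte genes (0.64 and -0.65) came to 0.083 without the same HSC library (adjusted p = 0.424), and in MPPs held in every fit, at -1.067 to -0.427. In GFP-low MPPs the glycolysis (-0.17) and inflammatory (-0.22) effects were lower, at -0.109 without KO 2 and -0.112 without KO 3 of those cells. HSC-enriched (-0.12) and megakaryocyte genes (-0.16) were also lower there, but 8 and 3 of 12 fits lost them. Without KO 2 of the GFP-high MPPs adjusted p was 0.506 and 0.103. B cell genes had the higher effect in GFP-low HSCs (1.65, and 1.079 without their KO 1), where the list did not pass (0.38). Under 5 were tested in GFP-high HSCs, so low values enter.

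The values of the 4 GFP populations were also averaged per replicate number, an analysis added after the data were seen. Gstm2 was higher by a mean log2 of 1.41 (SE 0.15, n = 3 each, adjusted p = 0.0219), Dok2 by 1.00 and Ptgds by 1.04. Cd24a (0.61, adjusted p = 0.0361) and the selenoprotein Selenom, listed as Selm in the first cohort (0.78, adjusted p = 0.0411), were among the rises that HSCs of the first cohort also showed. Ctsw (-1.06) and the histones H4c4 (-0.78), H2bc18 (-0.81), H2ac8 (-1.17) and H3c11 (-0.79) were lower. For the histones this again covers only RNA caught in polyA libraries. Of 10166 genes tested 24 passed, 15 higher and 9 lower. The count was 0 without WT 1, WT 2, WT 3 or labelled KO 2, 11 without labelled KO 1 and 91 without labelled KO 3. Replicate 2 of the labelled KO mice was male, with Ddx3y at 5.01 to 7.24 FPKM and Xist at 0.237 to 0.403, while all other libraries of both cohorts were female (Xist at 26.9 or more). Without that animal the 24 genes kept their direction, with adjusted p values of 0.0584 to 0.116 and Gstm2 at 1.29.

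Lists that passed in few or no comparisons complete the account. Genes of apoptosis passed in none (adjusted p from 0.342 to 0.835). The HIRA complex and H3.3 list passed in MPPs alone of the 6, with median log2 values of 0.07 in HSCs (adjusted p = 0.507), -0.08 and 0.04 in GFP-high and GFP-low HSCs and 0.03 and 0.07 in GFP-high and GFP-low MPPs. The median, the mean and the test's direction differed in sign for some lists, none of them past the test. These were HSC-enriched, mast cell, macrophage and B cell genes in GFP-low MPPs, neutrophil and p53 genes in HSCs and megakaryocyte genes in MPPs. The same held for p53, inflammatory and oxidative phosphorylation genes in GFP-high MPPs, apoptosis genes in GFP-high HSCs and ribosome biogenesis genes in GFP-low HSCs. The lists of T and NK cells and of sex-linked genes had under 5 tested members in every table and were not tested.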

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

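The tests in this part were chosen after the results were seen, except the count of genes near Hira and the splits for the gene lists, which were fixed before the data were examined. Regrouping the libraries tests whether any other division of the same libraries gives as many calls.

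In HSCs the 17 genes past the test were more than in any of the other 34 splits of the 8 libraries (highest 1). The 17 lists were also the most, but another split called 15. In MPPs the 15 genes were the most of 35 splits (highest of the others 2). For the 14 lists 3 of 35 splits gave as many (highest 15). First place in 35 splits is a share of 0.0286, the smallest that can be reached. It goes against chance for both gene counts without excluding it, and says little for the HSC lists. Any difference between the animals that runs with the labels would look the same. With 10 splits of 6 libraries, a share under 0.05 cannot be reached. The gene counts and their highest other split were 3 and 4 in GFP-high HSCs, 0 and 1 in GFP-low HSCs, 0 and 1 in GFP-high MPPs and 34 and 4 in GFP-low MPPs. The list counts were 13 and 13 in GFP-high HSCs, 13 and 13 in GFP-low HSCs, 15 and 13 in GFP-high MPPs and 10 and 15 in GFP-low MPPs. The other splits called a median of 8.5 lists in HSCs and 10 in MPPs. That median was 10 in GFP-high and GFP-low HSCs and 11 in GFP-high and GFP-low MPPs. Many lists thus pass at the preset correlation whatever the grouping. For the mean of the 4 GFP populations the gene counts were 24 and 0. For the difference of KO effects between GFP-low and GFP-high cells the counts were 0 and 0 in HSCs and 1 and 0 in MPPs. For the difference between HSCs and MPPs, 3 of 100 drawn splits, the real one included, gave at least 5 genes, and 1 split called 158. Other groupings can thus give as many, so chance is not excluded for this count. The split with 158 points to a structure of the samples other than the labels. What that structure is was not tested. The 5 became 0 without WT HSC replicate 2, labelled KO HSC replicate 4 or WT MPP replicate 2, and with the block described in the next part.

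The list of interferon-stimulated genes was lower in all 6 comparisons, with medians from -0.20 to -0.36. The 4 GFP comparisons share replicate numbers and are not independent. In 7 of the 9 other splits of the 6 numbers the 4 medians also had one sign, so their agreement adds little, though the smallest of the 4 was 0.174 in size at most there and 0.296 with the labels. In HSCs the next largest median of 35 splits was 0.199 in size, and in MPPs 3 of 35 splits were as large (highest 0.355). The values argue against 1 library as the cause (medians at most -0.166 in every fit without 1). They argue against the male labelled KO animal too (GFP medians at most -0.277 without it). They also argue against fewer macrophages, since that list fell by as much in 0 of 6. Fewer neutrophils stay open for HSCs, MPPs and GFP-low MPPs, where leaving out 1 library took their median to -0.348 or lower. Fewer B cells stay open for MPPs, since B cell genes were lower there (median -1.02, but -0.47 without WT replicate 2, adjusted p = 0.0946). That library alone was high in Igkc. The B cell list did not pass in GFP-high MPPs (-0.57), GFP-low MPPs (-0.43, of mixed sign) or GFP-low HSCs (0.38). In the other 2 comparisons under 5 were tested. Fewer antigen-presenting cells stay open, as MHC class II genes were lower in all 6 (medians -0.21 to -0.46). A smaller response to, or sooner recovery from, interferon after poly(I:C) in labelled KO cells stays open too. With no library without poly(I:C), a lower baseline cannot be set apart.

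Erythroid genes were higher in 5 of 6 comparisons. RNA of mature red cells would raise globin at least as much as the rest. In GFP-low MPPs the 2 globin genes rose by less than the other members (difference -0.63). This passed the bound set, the mean SE of the 2 globin genes (0.51). That SE leaves out the spread of the other 22 members, so with 3 libraries a side the difference does not decide on red cell RNA. In GFP-high MPPs and GFP-low HSCs the globin genes rose by more (0.57 and 1.35), so red cell RNA may account for part of the rise, and in GFP-high MPPs the list also turned to -0.25 without labelled KO replicate 3. In the other 4 comparisons no single library set the direction (lowest median 0.264). In HSCs and MPPs the globin difference (lower value -0.67) lay within the mean SE of the globin genes (1.05 in HSCs) and decides nothing. A shift toward erythroid fate or survival stays open as the biological explanation.

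Gstm2 was higher in labelled KO in all 6 populations, with no overlap in 5 (in MPPs the lowest labelled KO library held 0.752 FPKM and the highest WT library 0.826). Reads moved from paralogs at a steady level would take FPKM from the other Gstm genes, but their sum rose, by 19.9 FPKM in HSCs and by 36.5 to 71.0 elsewhere. In 0 of 6 comparisons did paralogs lose what Gstm2 gained. Reads spilling over from paralogs that themselves rose, as Gstm5 did in GFP-low MPPs, would leave that sum higher, so this stays open. A segment that came along with the floxed allele would lie near Hira on chromosome 16, and Gstm2 lies on chromosome 3. Another strain difference on chromosome 3 between the animals was not tested and stays open, so a response to the loss of HIRA may be offered as a hypothesis only.

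For genes within 10 Mb of Hira, 0 of 6 comparisons passed Fisher's exact test for more unadjusted p values under 0.05 than elsewhere. The share was higher near Hira in 4 of them, at 15.2% of 132 genes against 10.0% in HSCs (exact p = 0.0581), 11.5% against 10.3% in GFP-high HSCs, 8.8% against 7.1% in GFP-high MPPs and 15.7% against 12.2% in GFP-low MPPs. The bound fixed beforehand asked only that the test be missed, which a small excess also meets, so whether a segment around Hira differs between the animals stays open.

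Some values in groups of 4 came from 1 library far from the other 3, by the gap to the nearest library as a share of the range. In labelled KO HSCs these were Selm in replicate 1 (0.894, 20.8 against 17.4 to 17.8 FPKM), Ppbp in replicate 3 (0.86, 11.8 against 18 to 19.3) and Hist1h4m in replicate 4 (0.943, 27.3 against 20.5 to 20.8). The list levels of ribosome biogenesis and Myc targets (0.919, 4.60 against 4.90 to 4.93) and mitochondrially encoded genes (0.83, 11.5 against 10.9 to 10.95) stood apart in replicate 4. In WT HSCs these were H2-DMb1 in replicate 4 (0.841, 36.6 against 29.6 to 30.6) and Pfkl in replicate 3 (0.862, 23.4 against 27.7 to 28.4). In labelled KO MPPs these were H2-Eb1 in replicate 3 (0.972, 8.97 against 14.0 to 14.2) and mt-Nd6 in replicate 3 (0.858, 400.5 against 252 to 270). The 9 such groups of 202 tested are no more than chance gives (10.1).

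The KO effect differed between HSCs and MPPs for 1700003C15Rik (1.703), Gm43643 (2.613), RP23-92D22.3 (2.674), Tmem158 (1.306) and Mir3060 (-1.422), by limma's test of the difference. The first 3 held 0, 0 and 0.605 FPKM in WT HSCs, where no fall could be seen, so for them the test says nothing on how HSCs respond. Between GFP-low and GFP-high MPPs it differed for Mir7001 (2.444), a short RNA gene listed at 0 in 2 of the 4 groups, and the call was lost with a block by replicate number (adjusted p = 0.0516).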

How the results depend on the processing

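Alternatives added after the data or the unit were seen were the pseudocount, the rescaling to one total, quality weights, voom, the mean of the GFP populations and the refits of genes named later, and the others were planned. The planned settings for counts (another count model, another normalization) and tests across tables were not run.

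With a block by replicate number, 10 genes passed in HSCs, 137 in MPPs (88 higher and 49 lower, where the reported fit had 4 and 11), 2 in GFP-high HSCs (both lower, in place of the 3 higher ones), 52 in GFP-low MPPs, and 0 for the difference of KO effects between HSCs and MPPs (adjusted p of the 5 genes 0.103 to 0.134) and between GFP-low and GFP-high MPPs. The 2 falls in GFP-high HSCs were H2-Eb1 (adjusted p = 0.0253) and Cd74 (0.0347), and the 3 rises stood at 0.0749 to 0.0892. Whether the numbers pair WT with labelled KO (correlations of -0.12 to 0.28) or HSCs with MPPs (-0.17 to 0.28) is open. For the paired GFP libraries the block changed no other call. With no filter on low values 2 passed in HSCs, 0 in MPPs (limma) and 2 in GFP-low MPPs, where more genes are tested. A joint fit gave 9 in HSCs, 580 in MPPs (322 higher and 258 lower), 54 in GFP-low HSCs and 5 in GFP-high MPPs. A pseudocount of 0.1 gave 7 in MPPs and 1 for the difference between HSCs and MPPs, rescaling to one total 6 in HSCs, quality weights 33 in HSCs, 247 in MPPs, 5 in GFP-high HSCs and 3 in GFP-low HSCs, and voom 26 in HSCs and 107 in MPPs. The cause was not tested. Shared genes between HSCs and MPPs were 8 at an adjusted p under 0.1.

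All list calls in the 6 comparisons went to 0 with an estimated correlation (smallest adjusted p 0.123). With the block, 17, 14, 13, 14, 16 and 13 lists passed in the order of the report. With one total, 76 of 82 list calls passed and 3 medians changed sign.

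Without 1 library, HSCs gave 8 (without WT 1) to 17 genes, MPPs 0 (without WT 2) to 194 (without KO 4), GFP-high HSCs 0 to 2, GFP-low HSCs 0 to 9, GFP-high MPPs 0 to 3 and GFP-low MPPs 0 (without WT 3, KO 2 or KO 3) to 35. The difference between HSCs and MPPs gave 0 to 20, between GFP-low and GFP-high cells 0 in HSCs and 1 to 2 in MPPs, and the shared genes 0 to 3. List calls ranged over 13 to 19, 11 to 18, 11 to 14, 9 to 14, 12 to 16 and 7 to 14. Hira ranged from -0.179 to 0.009 in HSCs (turned without KO 3), -0.163 to -0.014 in MPPs, -0.362 to -0.037 in GFP-high HSCs, -0.235 to 0.19 in GFP-low HSCs (turned without KO 1, and at 0.083 with quality weights), 0.037 to 0.229 in GFP-high MPPs and -0.316 to -0.074 in GFP-low MPPs. Of the genes named by the rule, Hira alone changed direction in these fits. Of the 15 values of genes named later that were refitted in this way, S100a8 turned in GFP-low HSCs without KO 3 (-0.092), and Asf1b in HSCs, at -0.002, turned in 4 of 8 fits. For the mean of the GFP populations a pseudocount of 0.1 gave 23, and without 1 animal the count ranged from 0 to 91 (without KO 3).

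Depth limits genes of few reads, such as Hira (41 to 315 reads). Rescaling moved the median of all genes by under 0.1 (-0.065 to 0.085).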

Other observations

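The tests in this part were chosen after the results were seen.

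In MPPs 4 of the 15 genes past the test lie in one stretch of chromosome 5, with other tested genes between them. These are RP23-92D22.3 (19.7 FPKM in WT and 2.39 in labelled KO, log2 -2.82), Gm43643 (10.2 and 1.09), 1700003C15Rik (2.97 and 0.229) and Gm43492 (1.72 and 0.177). They include long noncoding RNAs and pseudogenes. Of 17 genes tested in this stretch (within 1 Mb of the 4), 15 were lower, from 10957406 to 11928740 on mm10, and 13 of these did not overlap between the groups. Among all genes tested in MPPs 9.92% did not overlap. The stretch was drawn around the 4 called genes, which are among the 13, so these counts are partly built in. The 15 summed to 61.7 ± 5.78 FPKM in WT MPPs and 11.4 ± 8.30 in labelled KO MPPs (SD, n = 4 each), with labelled KO replicate 4 highest at 23.7, while 11 of them listed in HSCs summed to 4.46 ± 1.04 and 4.47 ± 1.64. Whether the genes of this stretch resemble each other and share reads was not tested, so the number of separate genes is uncertain.

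Of the 17 genes that passed in HSCs, 12 were measured in the mean of the 4 GFP populations, and 11 had the same direction there. Another split of the 6 animals reached 11 as well, and 10 splits are too few for a share under 0.05. Of the 15 that passed in MPPs, 7 were measured and 4 had the same direction (highest of the other splits 7). Tspan8 rose in HSCs by 1.25 and stood at 1.05 in that mean (adjusted p = 0.112).

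The ribosomal RNA precursor Rn45s took a smaller share of all FPKM in labelled KO replicate 3 than in any other library of each GFP population. The share was 18.16% against 22.33% to 26.04% in GFP-high HSCs, 16.62% against 21.66% to 25.45% in GFP-low HSCs, 12.6% against 21.05% to 27.53% in GFP-high MPPs and 15.41% against 20.88% to 25.45% in GFP-low MPPs. In GFP-high MPPs all 3 labelled KO libraries (at most 22.46%) lay below all 3 WT libraries (at least 22.75%), and in the other 3 populations the groups overlapped. The same replicate held the high S100a8 values of GFP-low HSCs and GFP-high MPPs. Its cause was not tested.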
